A study of Mus musculus and Homo sapiens with 12 samples.

How the data were processed

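The series holds single-cell RNA sequencing of brains of mice injected with cells of the brain-metastatic human breast cancer lines MDA231-BrM or HCC1954-BrM. By the labels, brains were taken 4 weeks after injection (day 30 in the design text), dissociated, stained with hashtag antibodies and sorted as living cells (Calcein Violet positive, Annexin V negative) into cancer cells (GFP and mCherry positive), labeled stroma (mCherry positive only) and unlabeled stroma (negative for both). Of 12 samples, 6 are gene expression libraries and were used, 2 for each sorted group; the other 6 are hashtag libraries and were not used here. Libraries were made on the 10x Chromium instrument and sequenced on a NovaSeq.

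Per the deposited tables, the values are UMI counts per gene and barcode, with all barcodes kept and no normalization by the authors. The submitters' processing notes name hg38 as genome build for all samples; the symbols of the stromal libraries are those of mouse genes, written in capitals. The aligner and the gene annotation are not given in the sources used here. Stromal symbols were mapped to GENCODE M21 mouse names, which matched 96.8%, 96.6%, 96.5% and 96.4% of symbols in labeled stroma 1 and 2 and unlabeled stroma 1 and 2. Total UMIs were 197455824 and 123568642 in the cancer libraries, 103197837 and 72090993 in labeled stroma and 74235754 and 79194330 in unlabeled stroma. Intervals and limits given beside shares cover counting error only.

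Cells were barcodes with at least 1000 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. Doublets called by scrublet, as run in scanpy 1.11.5, were removed: 0 in labeled stroma 1, 21 (0.54%) in labeled stroma 2, 985 (7.73%) and 167 (2.05%) in unlabeled stroma 1 and 2, and 335 and 166 in the cancer libraries. The caller marked no cell of labeled stroma 1 and so did not work there. Stromal cells were clustered with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0). Malat1, mitochondrial genes and the ribosomal RNA genes Gm42418 and AY036118 were left out of the variable genes, because Gm42418 alone took 0.466%, 2.78%, 0.925% and 4.67% of UMIs in the stromal libraries. Clusters were named from marker lists by the class with the best score, at least 0.4, where the second class scored at most 0.7 times the best. These naming limits were set after the cluster scores were seen: a rule on z-scores lost a cluster of disease-associated microglia, and 0.7 admits a monocyte cluster while it leaves out a cluster between pericytes and endothelial cells. Cancer cells were assigned to 2 lines by k-means on marker genes of the lines, which were left out of all tests between them; 97 and 121 HCC1954-BrM-like and 101 and 67 MDA231-BrM-like cells lay near the boundary. Cancer cluster 6 (840 cells, median 1692 UMIs, 40.8% HCC1954-BrM-like) stayed ambiguous. Cancer clusters were described at resolution 0.5.

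Counts were summed per library and class for classes with at least 50 cells in each stromal library: microglia, astrocytes, endothelial cells and ependymal cells. Labeled and unlabeled stroma were compared with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit, glmQLFTest; R 4.3.3), with Benjamini-Hochberg adjustment at 0.05. Class shares were tested with the same model on cell counts. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation. The lists covered homeostatic and disease-associated microglia, type I interferon, MHC class I and II, cytokines, proliferation, glycolysis and hypoxia, oxidative phosphorylation, cholesterol, lysosome, dissociation stress, reactive astrocyte, astrocyte homeostasis, blood-brain barrier, tip cells, endothelial adhesion, extracellular matrix and ribosomal proteins, and for the cancer lines also keratins, mesenchymal genes, NF-kB, brain colonization and ERBB signalling. The difference in labeling effect was tested as an interaction in edgeR with library as a block, for the 2 stromal classes with the most cells. HCC1954-BrM-like and MDA231-BrM-like cells were compared with edgeR on counts summed per cancer library and line. The main fit had no block and so ignores that each library holds both lines, and the library as a block was an alternative. DESeq2 1.42.0 was run beside edgeR. Biological coefficients of variation were 29.1% in microglia, 26.8% in astrocytes, 23.8% in endothelial cells, 26.9% in ependymal cells and 20.8% in cancer cells. Figures were drawn with matplotlib 3.10.9.

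The numbers 1 and 2 pair the samples, since libraries of a number share a project number in the deposited names; this pairing was settled before calls were compared. The deposited names of all 3 set 2 libraries also carry tags for a day and a condition that set 1 names lack and that no label explains. Whether set 2 differed in time or treatment is not known, and differences between the sets, and what the block removes, can include it. Checked across genes, which are not independent replicates, the differences between sets 1 and 2 in labeled and in unlabeled cells correlated at 0.56 in microglia, 0.17 in astrocytes, 0.27 in endothelial cells, 0.49 in ependymal cells and 0.34 between the cancer lines. Calls come from the fit without a block, and values with library number as a block are given beside it. Tests, filters, cell markers, gene lists and the naming rule were chosen before the data were examined. The rule names, among called genes with mean log2 CPM of at least 5 and the same sign in both sets, the 12 with the largest change in each direction, and up to 4 members of each list by smallest adjusted p. Genes named from the blocked fit follow the same rule but were chosen after their values were seen, because the fit without a block called 0 genes in microglia and in ependymal cells. Free RNA was estimated per class and library from barcodes of 20 to 99 UMIs, as the median over markers of other classes with at least 50 UMIs in them, and subtracted as an alternative.

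The tests were tested on simulated data with known changes, made only in genes with mean log2 CPM of at least 5. Without the block, and for the interaction, counts were drawn from mean levels and the fitted dispersion trend, with no difference between sets. Recovery there need not hold for the files, where the sets differed. Of 100 genes changed 2-fold, edgeR recovered 12% in microglia, 17% in astrocytes, 26% in endothelial cells and 8% in ependymal cells, and with the block 91%, 34%, 70% and 66%. Of 100 genes changed 4-fold it recovered 95%, 91%, 96% and 83%, and with the block 100%, 97%, 100% and 99%. Between the cancer lines it recovered 56% at 2-fold and 100% at 4-fold, and for the interaction 6% and 45%. Unchanged genes were 3% to 6.6% of those called by edgeR and up to 15.3% of those called by DESeq2. With the block, set differences were simulated as in the files, but each labeling change was the same in both sets. In the files the labeling differences of sets 1 and 2 correlated across genes at 0.51 in microglia, 0.26 in astrocytes, 0.54 in endothelial and 0.47 in ependymal cells. Recovery and error shares with the block therefore need not hold there either. Alternatives were the block, DESeq2 size factors, no filter on low counts, DESeq2, UMI minimums of 500 and 2000, a mitochondrial limit of 10%, doublets kept, Leiden resolution 2, an estimated correlation, free RNA subtracted and leaving out each library. A doublet score under 0.25, leaving out Gm42418 and AY036118, adding cycling clusters and leaving out cancer cells near the boundary were chosen after seeing the data, as was the application of some alternatives to the gene lists and the interaction.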

Results

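Cells of the brain-seeking breast cancer lines MDA231-BrM and HCC1954-BrM were grown in mouse brains and sorted together with host cells, 4 weeks after injection by the sample labels. The cancer cells carried GFP and mCherry, and in niche labeling of this kind they release mCherry that cells near them take up. Host cells with mCherry are called labeled stroma and host cells without it unlabeled stroma. Cancer cells, labeled stroma and unlabeled stroma each had 2 single-cell RNA libraries, numbered 1 and 2. The hashtag libraries that mark each brain were not used here, so stromal values cannot be separated by cancer line. The comparisons ask which host cells carried the label and how their gene levels differed from unlabeled cells of the same class. They also ask how the cancer lines differed. The label marks uptake of mCherry, and neither distance to cancer cells nor capacity for uptake was measured. After filtering, labeled stroma 1 and 2 held 12743 and 3861 cells, unlabeled stroma 1 and 2 held 11757 and 7970, and the cancer libraries held 9458 and 7028. Each gene value below is a log2 fold change over 2 libraries per group, and levels are UMI counts scaled to library size (CPM). The standard error (SE) of a value is its size divided by the square root of the edgeR test statistic. That statistic draws on dispersion shared across genes, so SE and p do not rest on the spread of that gene alone. P-values measure spread between libraries only, since nothing in the labels says that the libraries came from separate animals, and set 2 is not known to match set 1 in time or treatment, because its deposited names carry tags that no label explains.

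Microglia, the resident macrophages of the brain, made up 74.3% (95% exact Clopper-Pearson interval 73.5 to 75) and 38.0% (36.4 to 39.5) of labeled stroma 1 and 2. In unlabeled stroma 1 and 2 they made up 19.5% (18.8 to 20.2) and 2.82% (2.47 to 3.21). Border-associated macrophages, which line vessels and meninges, were 4.45% (4.10 to 4.82) and 4.82% (4.16 to 5.54) of labeled cells but 0.085% (0.041 to 0.156) and 0.013% (at most 0.07) of unlabeled cells. Microglia in the cell cycle were 3.59% (3.28 to 3.93) and 10.4% (9.44 to 11.4) of labeled cells, against 0.094% (0.047 to 0.167) and 0.301% (0.193 to 0.448). Oligodendrocyte precursors were 0.887% (0.731 to 1.07) and 7.38% (6.58 to 8.25) of labeled cells, against 0.034% (0.009 to 0.087) and 0.427% (0.296 to 0.596). Endothelial cells, which line blood vessels, were 0.471% (0.359 to 0.606) and 5.13% (4.45 to 5.87) of labeled cells, against 10.7% (10.2 to 11.3) and 20.7% (19.8 to 21.6). Astrocytes, the main support cells of neurons, were 0.455% and 14.3% of labeled cells and 4.49% and 55.4% of unlabeled cells. Smooth muscle cells were 0.039% of labeled stroma 1 and 0% of labeled stroma 2 (limit 0.078%), against 26.8% and 0.866% of unlabeled cells. Choroid plexus cells, which make the cerebrospinal fluid, were 0% (limit 0.024%) and 0.052% of labeled cells, against 2.06% and 2.72%.

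With the library number as a block, the shares of 9 of 22 classes differed, 3 up and 6 down, in an edgeR test on cell counts. Border-associated macrophages had a log2 difference of 6.75 ± 1.44 (adjusted p = 0.000932, edgeR), cycling microglia of 5.17 ± 1.3 (0.00342) and oligodendrocyte precursors of 4.35 ± 1.26 (0.0103). Smooth muscle cells fell by 9.36 ± 1.82 (adjusted p = 0.000794, edgeR), a size resting mostly on unlabeled stroma 1, where they were 26.8% of cells against 0.866% in unlabeled stroma 2. Choroid plexus cells (-7.25 ± 1.56, 0.000932), endothelial cells (-3.25 ± 1.24, 0.038) and neurons (-4.47 ± 1.47, 0.0161) fell as well. Neurons were 3.96% of unlabeled stroma 1 but 0.289% of unlabeled stroma 2, against 0.071% and 0.052% of labeled cells, so the value rested mostly on the first. Oligodendrocytes (-5.23 ± 1.69) and neural progenitors (-6.38 ± 1.92) rested on unlabeled stroma 1, where they were 9.01% and 8.38% of cells, and without that library the unblocked differences were 1.69 and 5.16. The rise of microglia (2.84 ± 1.19, adjusted p = 0.0572, edgeR) and the astrocyte difference (-2.62 ± 1.16, 0.0691) did not pass, and without unlabeled stroma 2 the astrocyte difference turned to 0.71. Without the block, edgeR called 0 of 22 classes, with 7 under an unadjusted p of 0.05, and an exact permutation of 2 against 2 libraries cannot give a p under 0.33. Shares also carry the sort and a depth gap, with median UMIs per cell of 5986 and 13262 in labeled and 4211 and 6638 in unlabeled stroma. Clusters that met no class definition held 4.94% and 8.94% of labeled and 2.95% and 7.04% of unlabeled cells.

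**Figure D1:**
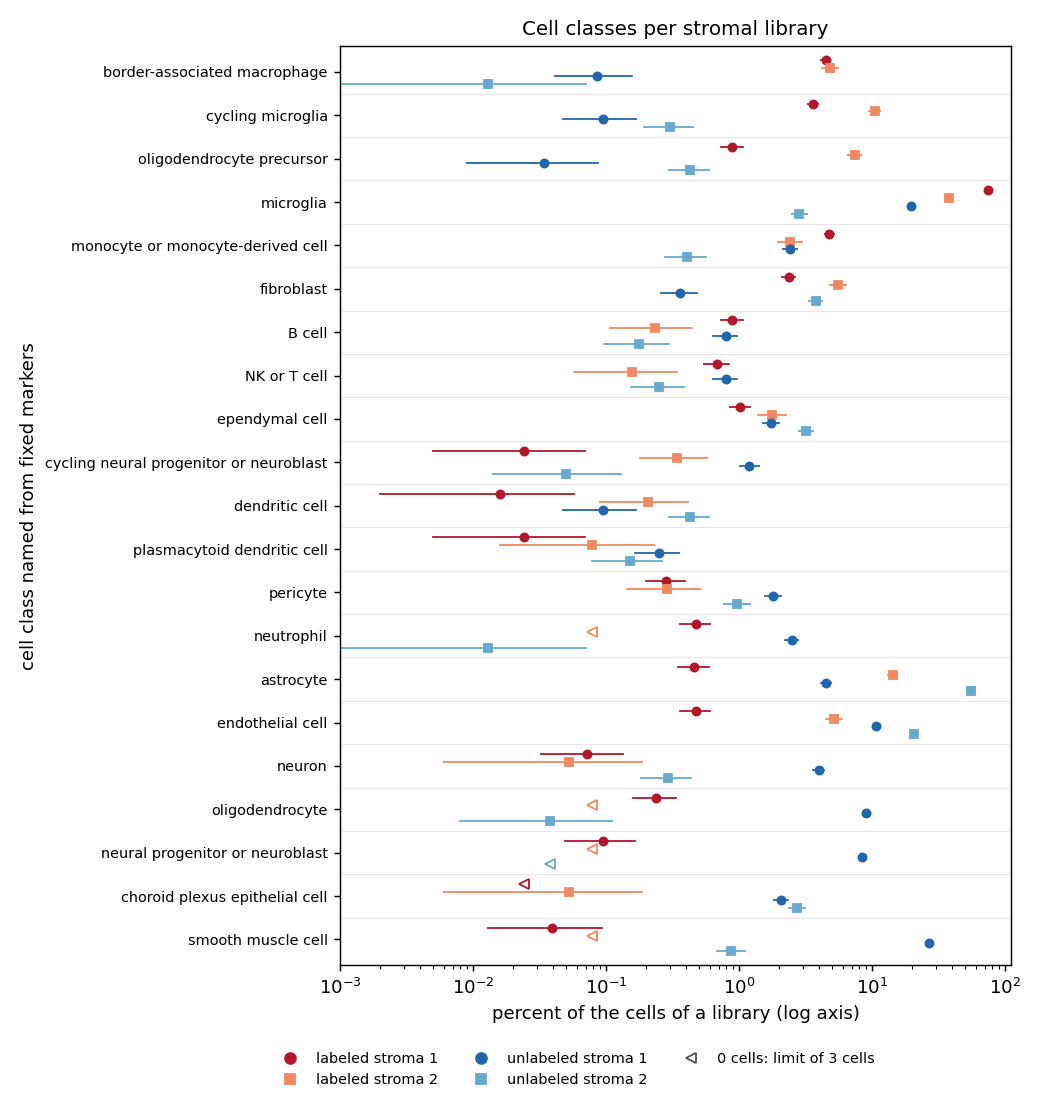
Share of cells in percent (log axis) for the cell classes of labeled and unlabeled stroma; each point is 1 library with its 95% exact interval, and open triangles mark the limit from 3 counts where 0 cells were found. Border-associated macrophages were 4.45% and 4.82% of labeled cells and at most 0.085% of unlabeled cells.

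Endothelial cells of labeled stroma had lower levels of 5 genes of the fixed blood-brain barrier list. Slco1a4, an organic anion transporter, fell by 2.16 ± 0.17 (adjusted p = 0.0468, edgeR), from 2029 and 2011 CPM in unlabeled to 421 and 415 CPM in labeled cells. The drug efflux pumps Abcb1a (-1.68 ± 0.23) and Abcg2 (-1.45 ± 0.19), the phospholipid carrier Pltp (-1.37 ± 0.18) and the glucose transporter Slc2a1 (-1.25 ± 0.18) fell as well, the last from 2457 and 2187 to 889 and 911 CPM. Of 11035 genes tested, edgeR called 73, of which 10 rose and 63 fell, in 60 and 198 labeled against 1262 and 1650 unlabeled endothelial cells. Apart from Ttr, the largest falls among called genes that met the naming rule began with Plvap, which forms the diaphragms of leaky vessels. It fell by 4.00 ± 0.48, from 68.1 and 49.9 to 0 and 4.0 CPM. Next were the Wnt-inactivating enzyme Notum (-3.78 ± 0.32) and the peptide gene Edn3 (-3.58 ± 0.46). They were followed by the chaperone Clu (-3.56 ± 0.51), the enzymes Ddc (-3.45 ± 0.41), Xdh (-3.39 ± 0.35), Ephx1 (-3.22 ± 0.32), Degs2 (-2.96 ± 0.35) and Galnt15 (-2.63 ± 0.32), the metallothionein Mt2 (-3.24 ± 0.29) and the guidance gene Sema3c (-2.45 ± 0.20). Clu is also a leading gene of astrocyte cluster 2. Ttr, the main product of the choroid plexus, had no counts in labeled endothelial cells against 268 and 91.7 CPM in unlabeled ones. The genes that rose most were the actin-binding Cotl1 (2.49 ± 0.30), the sulfotransferase Chst7 (2.27 ± 0.28), the phosphatase Ptpn18 (2.08 ± 0.29) and the interferon-induced Ifi27l2a (2.05 ± 0.28). The phosphatase inhibitor Ppp1r14b rose by 1.65 ± 0.23, the lectin Clec1a by 1.46 ± 0.21, Fam167b by 1.44 ± 0.20 and the ribosomal gene Rplp0 by 1.22 ± 0.17. The naming rule admitted 9 rising genes, not all of which are named here. Adjusted p-values of the called genes named here were 0.0468 or 0.0485 (edgeR). Without labeled stroma 1 or without labeled stroma 2 only 2 genes passed and 0 of the 73 were among them, while 67 passed without unlabeled stroma 1 and 376 without unlabeled stroma 2. With the library number as a block 1700 genes passed (986 up, 714 down), among them all 73 in the same direction. The 73 calls went to 0 with doublets kept, to 5 with a mitochondrial limit of 10%, to 5 at Leiden resolution 2 and to 37 with a doublet score under 0.25.

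Among lists fixed beforehand, the blood-brain barrier list lay lower in labeled endothelial cells (camera, adjusted p = 9.45e-11, and 0.615 with an estimated correlation between genes, where no endothelial list passed), with medians of -1.40 and -1.10 in sets 1 and 2. Of its 22 measured members 5 fell, 16 fell when adjusted over the list alone, and 20 fell with the block. The angiogenesis and tip cell list lay higher (adjusted p = 1.2e-05, camera), with medians of 1.83 and 1.04, although 1 member fell and 0 rose without the block; adjusted over the list alone 10 rose and 1 fell. With the block 16 of its 21 members rose, led by Trp53i11 (2.96 ± 0.31, adjusted p = 4.07e-06, edgeR), the adhesion gene Mcam (2.07 ± 0.22, 5.35e-06) and the basement membrane collagen Col4a1 (1.70 ± 0.20, 1.52e-05). Cluster 19, led by Ctla2a, Cd93, Apln and Col4a1, held 93.3% and 81.8% of labeled endothelial cells, and cluster 4, led by Slco1a4 and Cxcl12, held 63.4% and 69.2% of unlabeled ones. Ribosomal proteins (5.77e-11), glycolysis and hypoxia (0.00043), oxidative phosphorylation (0.0262) and extracellular matrix (0.00383; 0.336 without labeled stroma 1) also lay higher, and with the block 30 of 30, 14 of 24, 2 of 26 and 9 of 19 members rose. In the matrix list Sparc rose with the block (1.32 ± 0.15), and in the glycolysis list the hypoxia gene Ndrg1 fell (-1.86 ± 0.18). Oxidative phosphorylation was lost without labeled stroma 1 (0.0745) or unlabeled stroma 2 (0.233). The endothelial adhesion list did not move as a set (0.917, with a positive median of 0.21 against a negative test), yet with the block the leukocyte adhesion gene Vcam1 fell by 1.23 ± 0.18 (adjusted p = 0.000108, edgeR) and the NF-kB inhibitor Nfkbia by 0.85 ± 0.13. Type I interferon did not pass (0.0504), passing with the block (0.0244), without labeled stroma 1 (0.000546) and without unlabeled stroma 2 (0.000184). MHC class I (0.497; 0.0319 without unlabeled stroma 2), cytokines (0.155; 0.00625 with the block, 0.00298 without labeled stroma 2 and 0.0352 without unlabeled stroma 1), proliferation (0.155; 0.0416 with the block, 3.12e-05 without labeled stroma 1 and 0.00459 without unlabeled stroma 2) and stress genes (0.807; 0.0131 without labeled stroma 2) did not pass. Cholesterol handling (0.477) and the reactive astrocyte list (0.929) did not pass either.

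Genes of other cell types moved in endothelial cells too. Of 9 measured microglial markers, 9 rose with the block (median 2.39), and these markers took 0.629% and 0.586% of UMIs in labeled against 0.193% and 0.341% in unlabeled endothelial cells. In low-UMI barcodes they took 0.655% and 0.417% in labeled and 0.316% and 0.133% in unlabeled stroma. The endothelial share was thus above that of free RNA in set 2 but not in set 1. The marker list, here and in the other classes, holds Sparc, which is also the matrix gene named above. Count and share therefore need not come from microglial RNA alone. The microglial lists for homeostasis (6.86e-05), disease association (0.000857; 0.19 without labeled stroma 1), lysosome (3.94e-06) and MHC class II (0.038; 0.24 without unlabeled stroma 2) lay higher in labeled endothelial cells (camera, adjusted p). Complement C1qa had 866 and 228 CPM in labeled and 76.4 and 7.0 CPM in unlabeled endothelial cells (4.30 ± 0.26 with the block). Of 9 astrocyte markers, 7 fell with the block (median -2.37), and the astrocyte homeostasis list lay lower (0.00128). After subtraction of a free-RNA profile the homeostatic (0.381) and disease-associated (0.383) lists no longer passed, astrocyte homeostasis (0.698) and MHC class II (0.964) changed direction and were lost, and most astrocyte markers were too low to give a value. The barrier genes kept their calls for Slco1a4 (-2.13) and Slc2a1 (-1.23).

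**Figure D2:**
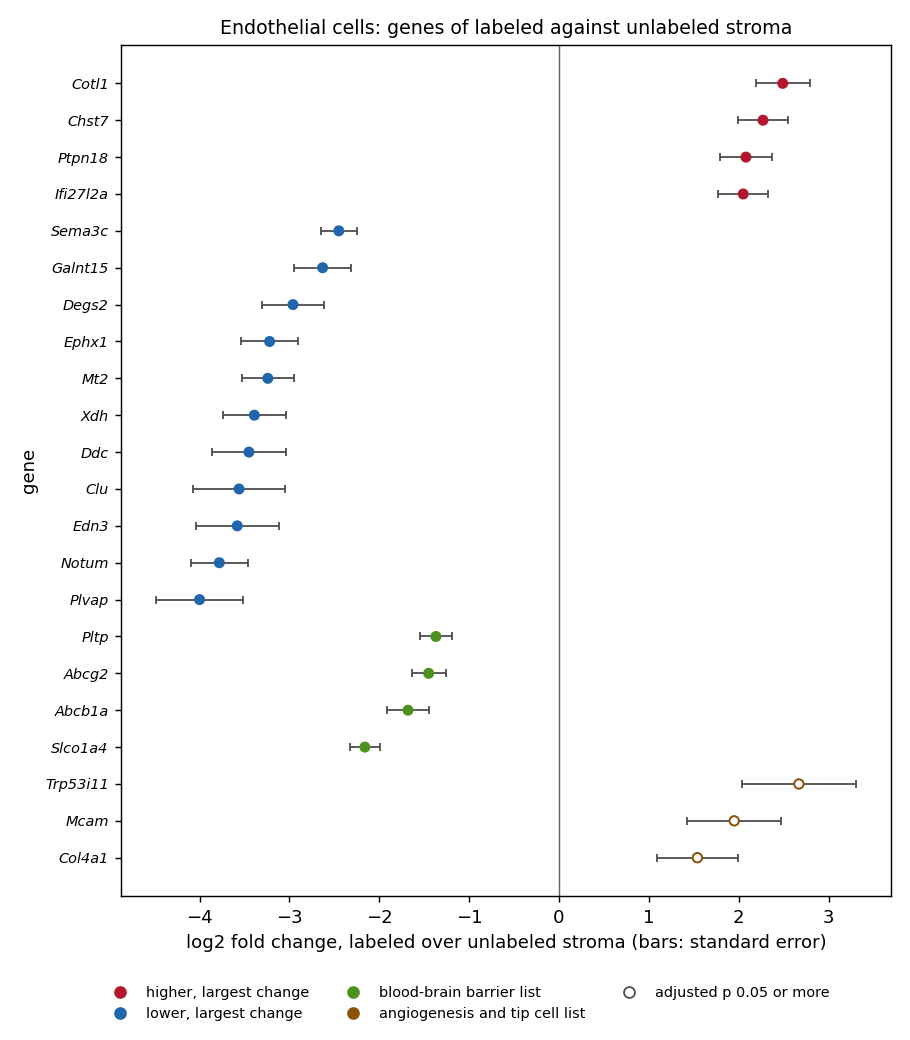
Log2 fold change, labeled over unlabeled, of endothelial genes in the fit without a block, with SE as bars; open circles are tip cell list members with an adjusted p of 0.05 or more. Slco1a4 lay at -2.16 ± 0.17 and Cotl1 at 2.49 ± 0.30.

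Astrocytes of labeled stroma had higher levels of 10 genes, among them Isg15, Ifit1, Lgals3 and Lgals1. Isg15, an interferon-induced ubiquitin-like protein, rose by 2.85 ± 0.38 (adjusted p = 0.0315, edgeR), from 6.2 and 11.7 to 67.5 and 75.4 CPM, and Ifit1, an antiviral RNA-binding protein, by 2.79 ± 0.38 (0.0322). The galectins Lgals3 (3.26 ± 0.48) and Lgals1 (2.34 ± 0.34) rose with an adjusted p of 0.0388 (edgeR). Lgals3 is also a member of the disease-associated microglia list. Fbln2, a matrix protein, rose by 3.68 ± 0.42 (adjusted p = 0.00903, edgeR), but the value turned to -0.62 with a mitochondrial limit of 10% and to -0.54 with a doublet score under 0.25. Of 11820 genes tested in 58 and 551 labeled against 528 and 4413 unlabeled astrocytes, edgeR called 13, of which 10 rose and 3 fell. The other 5 that rose had lower levels and were named after their values were seen: Sulf2 (3.43 ± 0.36), Ifi202b (4.60 ± 0.52), Ifitm10 (4.38 ± 0.65), Cp (2.88 ± 0.43) and Fn1 (2.54 ± 0.38). Fn1 is also among the fixed monocyte markers. The 3 that fell were nearly without counts in labeled astrocytes: Ttr had 0 and 0.2 against 274 and 91.3 CPM, the sodium channel gene Scn7a 0 and 0.4 against 25.3 and 42 CPM, and the collagen Col25a1 0 and 0.2 against 17.6 and 31.8 CPM. With the library number as a block 550 genes passed (340 up, 210 down), among them the same 13; the filament genes Nes (2.73 ± 0.38, adjusted p = 2.97e-10, edgeR) and Vim (2.18 ± 0.31), the protease inhibitor Timp1 (2.48 ± 0.37) and the interferon-induced Ifitm3 (2.16 ± 0.28) rose. The Notch target Hes5 fell by 2.73 ± 0.31 (adjusted p = 1.07e-15, edgeR), the potassium channel Kcnk1 by 2.67 ± 0.37 and the lipid transporter Mfsd2a by 2.09 ± 0.30. Calls numbered 349 without labeled stroma 1, 464 without labeled stroma 2, 129 without unlabeled stroma 1 and 53 without unlabeled stroma 2, with 13, 10, 13 and 9 of the 13 among them. The count was 0 with a mitochondrial limit of 10%, 0 with a doublet score under 0.25, 1 with doublets kept and 4 at a UMI minimum of 500. Both doublet settings treat the libraries alike, whereas the caller had removed 0% of labeled stroma 1 and 7.73% of unlabeled stroma 1.

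The type I interferon list gave the smallest p in astrocytes (camera, adjusted p = 2.18e-24, and 0.276 with an estimated correlation, where no astrocyte list passed), with medians of 2.43 and 1.73; 2 of 22 members rose, 19 rose adjusted over the list alone, and 15 rose with the block. The reactive astrocyte list lay higher (5.26e-10), with 1 of 22 members up, 17 adjusted over the list alone and 18 with the block, among them Tm4sf1 (3.44 ± 0.40) and Cxcl10 (3.05 ± 0.36). The astrocyte homeostasis list lay lower (0.00182; 0.152 without unlabeled stroma 2), and with the block 5 of 20 members fell, among them the amino acid transporter Slc7a10 (-1.13 ± 0.29) and the protease Htra1 (-1.17 ± 0.32). MHC class I (3.75e-08), proliferation (3.96e-10), ribosomal proteins (7.13e-14) and extracellular matrix (0.000293) lay higher, and with the block 5 of 15, 5 of 13, 10 of 30 and 7 of 19 members rose. Stress genes (7.47e-07) lay higher but not without labeled stroma 1 (0.135) or unlabeled stroma 2 (0.0745). Cytokines (0.00527; 0.129 and 0.0745 without these libraries) and MHC class II (0.00309; 0.134 and 0.522) were lost in the same way, and endothelial adhesion genes (0.0026) without unlabeled stroma 2 (0.0745). Microglial markers also rose in astrocytes with the block, 6 of 10 (median 1.92), and took 0.368% and 0.182% of UMIs in labeled against 0.154% and 0.135% in unlabeled astrocytes. The disease-associated (3.64e-09), homeostatic (0.00158; 0.267 without labeled stroma 1) and lysosome (0.000685; 0.0595 without labeled stroma 1) lists lay higher, with C1qa at 1202 and 134 CPM in labeled and 87.8 and 7.3 CPM in unlabeled astrocytes. After subtraction of free RNA the homeostatic microglia (0.558), lysosome (0.853) and cytokine (0.558) lists no longer passed in astrocytes. The disease-associated microglia list still passed after it (camera, adjusted p = 0.000415). Glycolysis (0.706), cholesterol handling (0.0902; lower at 0.0223 after subtraction of free RNA) and tip cell genes (0.955) did not pass; oxidative phosphorylation (0.965, with a negative median of -0.03 against a positive test) passed as lower without labeled stroma 1 (0.0156), and blood-brain barrier genes (0.0902) without labeled stroma 1 (0.000692) and without unlabeled stroma 1 (0.00525). Cluster 7, led by Gdf10 and Gria4, held 74.1% and 33.6% of labeled astrocytes, and cluster 2, led by Slc1a2 and Cspg5, held 27.5% and 45.0% of unlabeled ones.

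Microglia of labeled stroma had 0 genes past the threshold of 12111 tested by edgeR, with 1562 under an unadjusted p of 0.05 and 223 called by DESeq2 (211 up, 12 down). DESeq2 gave no adjusted p for 10331 of these genes. With the library number as a block 2127 genes passed, 1167 up and 960 down. The acute phase gene Saa3 rose by 6.34 ± 0.25 (adjusted p = 3.44e-09, edgeR with the block), from 2.2 and 0.9 to 141 and 24.9 CPM. Saa3 and Ccl8 are also among the leading genes of cluster 20, the border-associated macrophages, which were more frequent in labeled stroma. The interferon-induced genes Rsad2 (2.81 ± 0.39), Ifitm3 (2.40 ± 0.51), Irf7 (2.34 ± 0.47), Iigp1 (2.33 ± 0.20) and Slfn5 (2.19 ± 0.31) rose. The chemokines Cxcl9 (2.78 ± 0.34), Cxcl13 (2.60 ± 0.74), Cxcl10 (2.49 ± 0.28) and Ccl5 (2.45 ± 0.75), the lipoprotein Apoc1 (2.21 ± 0.33) and osteopontin, Spp1 (2.25 ± 0.71), completed the largest rises among genes that met the naming rule. Hpgd, which degrades prostaglandins, fell by 1.97 ± 0.14 (adjusted p = 1.03e-06, edgeR with the block), from 118 and 98.4 to 23.3 and 20.3 CPM. Il7r (-1.28 ± 0.15), Csmd3 (-1.18 ± 0.16) and Sox4 (-1.39 ± 0.18) fell, as did Ddit4 (-2.40 ± 0.36), Tsc22d3 (-1.44 ± 0.22), Adrb1 (-1.37 ± 0.18) and Crip1 (-1.32 ± 0.24). In the unblocked fit without unlabeled stroma 1, Ddit4 turned to 0.80, Tsc22d3 to 1.07 and Adrb1 to 0.02, and after subtraction of free RNA Crip1 turned to 0.91. The purine receptor P2ry12, a marker of resting microglia, had 689 and 816 CPM in labeled and 1729 and 1705 CPM in unlabeled microglia and was not called (adjusted p = 0.112, edgeR with the block). Unblocked counts were 3 without unlabeled stroma 1, 175 without unlabeled stroma 2 and 0 without either labeled library.

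The homeostatic microglia list lay lower in labeled microglia (camera, adjusted p = 2.86e-06, and 0.502 with an estimated correlation, where no microglial list passed), with medians of -0.58 and -0.45, and 3 of 20 members fell with the block, among them the sugar transporter Slc2a5 (-1.09 ± 0.13) and the receptors Gpr165 (-2.01 ± 0.43) and P2ry13 (-0.65 ± 0.20). Type I interferon (1.28e-07) lay higher with medians of 2.84 and 0.79, and 25 of 26 members rose with the block. Glycolysis and hypoxia (1.51e-09) lay higher with medians of 1.59 and 0.73; 0 of 24 members rose without the block, 16 adjusted over the list alone and 17 with the block, led by the lactate transporter Slc16a3 (1.24 ± 0.15) and Bnip3 (1.24 ± 0.16). Oxidative phosphorylation (6.43e-11), ribosomal proteins (7.24e-15) and MHC class I (9.01e-07) lay higher, and with the block 16 of 26, 2 of 30 and 9 of 16 members rose, among them Atp5g1 (1.00 ± 0.22) and H2-Q7 (1.15 ± 0.21). Disease-associated microglia genes lay higher (6.26e-06), and 7 of 27 rose with the block, among them the fatty acid carrier Fabp5 (2.12 ± 0.22), Gpnmb (4.08 ± 0.61) and Lgals3 (1.63 ± 0.38); without unlabeled stroma 1 this list (0.0774), proliferation (3.81e-05 to 0.0681), cholesterol handling (0.00158 to 0.191) and lysosome (0.00156 to 0.309) were lost. Cytokines and chemokines lay higher (0.000488; 0.0676 without labeled stroma 1), and Ccl8 (4.27 ± 0.33), Il12b (3.17 ± 0.32) and Ccl2 (1.96 ± 0.33) rose with the block. MHC class II (0.0359) was lost without labeled stroma 1 (0.115), without unlabeled stroma 1 (0.939) or after subtraction of free RNA (0.0703), and endothelial adhesion genes (0.0392) without labeled stroma 1 (0.602) or unlabeled stroma 2 (0.209). Reactive astrocyte (0.177; higher at 0.0125 after subtraction of free RNA) and extracellular matrix genes (0.834, with a negative median of -0.20 against a positive test) did not pass. Stress genes (0.583, with a negative median of -0.56 against a positive test) passed as lower without labeled stroma 1 (0.039) or unlabeled stroma 2 (0.0177) and as higher without labeled stroma 2 (0.000991) or unlabeled stroma 1 (0.000502).

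Markers of other cell types moved both ways in labeled microglia. Of 10 astrocyte markers, 8 fell with the block (median -2.30), and 5 of 5 smooth muscle markers fell (median -7.00), with Acta2 at 0.8 and 0.2 against 157 and 0.5 CPM and Ttr at 4.9 and 0.4 against 272 and 85.3 CPM. Without unlabeled stroma 1 the Acta2 value turned to 0.47. The lists for astrocyte homeostasis (3.58e-10), blood-brain barrier (6.43e-11) and tip cells (0.00358) lay lower. After subtraction of free RNA the first changed direction and was lost (0.909), the last was lost (0.642), and most of the astrocyte markers gave no value. Of 7 border-associated macrophage markers, 5 rose with the block (median 2.16), as did 3 of 6 monocyte (0.72) and 2 of 3 plasmacytoid dendritic cell markers (0.98). Microglia of labeled stroma 1 were spread over several clusters, the largest being cluster 1 (30.8%), led by Spp1, Cd72 and Cxcl13, and those of labeled stroma 2 sat mostly in cluster 8 (59.5%), led by Cst7 and Mpeg1. Unlabeled stroma 1 sat mostly in cluster 0 (73.5%), led by Jun, Egr1 and P2ry12, and unlabeled stroma 2 in cluster 17 (52.4%), led by P2ry12 and Gpr34. Among the other microglial clusters, 6 was led by Tnf, Atf3 and Ccl4, 15 by Cxcl10, Rsad2 and Ifit2, and 16 by Ccl12, Ccl2 and Il1a. The microglial interferon list had an adjusted p = 0.513 with an estimated correlation (camera).

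**Figure D3:**
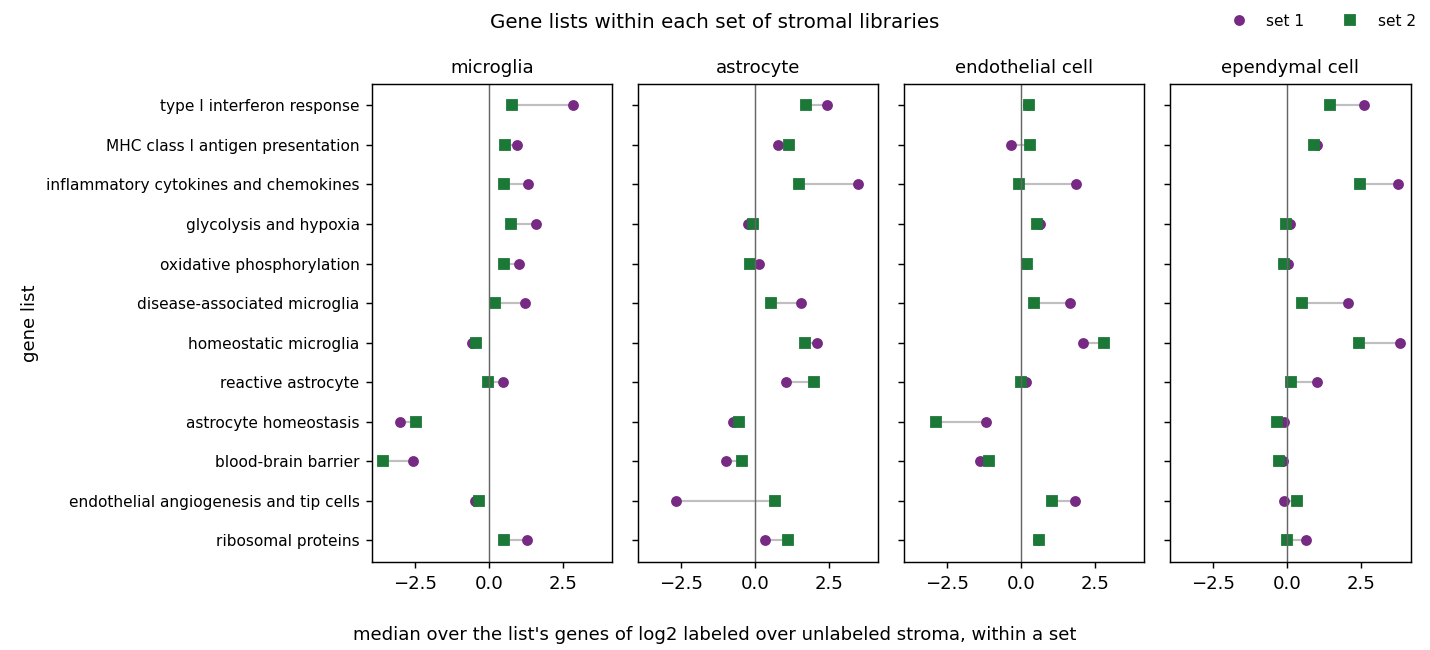
Median log2 difference, labeled over unlabeled, of 12 fixed gene lists in each of 4 cell classes; circles are set 1 and squares are set 2. The interferon medians were 2.84 and 0.79 in microglia and 2.43 and 1.73 in astrocytes.

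Ependymal cells, which line the ventricles, had 0 genes past the threshold of 9937 tested by edgeR, with 418 under an unadjusted p of 0.05 and 27 called by DESeq2. With the library number as a block 192 passed, 176 up and 16 down; unblocked counts were 111 without labeled stroma 2, 36 without unlabeled stroma 1 and 0 without either of the others. The interferon gene Ifit3 rose by 2.70 ± 0.26 (adjusted p = 5.13e-05, edgeR with the block), and Cxcl10 had 3 counts in all in unlabeled ependymal cells against 71 and 64 counts in labeled ones. The type I interferon list lay higher (camera, adjusted p = 1.59e-37, and 0.438 with an estimated correlation, where no ependymal list passed), with medians of 2.61 and 1.45 and 18 of 23 members up with the block. Lysosome (1.43e-18), homeostatic microglia (2.95e-16), disease-associated microglia (2.73e-10), MHC class I (9.81e-09) and reactive astrocyte (4.06e-08) lists lay higher. After subtraction of free RNA these lists still passed (camera, adjusted p). They gave 2.4e-07 for lysosome, 0.000146 for homeostatic and 3.61e-06 for disease-associated microglia, 0.000772 for MHC class I and 3.74e-09 for reactive astrocyte. With the block 8 of 10 microglial markers rose (median 4.5), most of which gave no value after that subtraction. Free RNA was estimated at 24.7% and 10.9% of UMIs in labeled and 6.19% and 9.51% in unlabeled ependymal cells. Without labeled stroma 1 the calls for MHC class II (0.000407 to 0.231), cytokines (0.00419 to 0.885), stress genes (0.00861 to 0.31), astrocyte homeostasis (lower, 0.00635 to 0.107) and endothelial adhesion (0.032 to 0.127) were lost, and ribosomal proteins (0.00434) turned to lower (0.0243). Without unlabeled stroma 2 stress genes, astrocyte homeostasis and ribosomal proteins were lost as well (0.881 each). Blood-brain barrier genes lay lower (0.0345), but after subtraction of free RNA they changed direction and were lost (0.815), astrocyte homeostasis turned to higher (0.00174), and cytokines (0.815), ribosomal proteins (0.815) and endothelial adhesion (0.0787) were lost. Proliferation (0.264; 0.0469 without unlabeled stroma 1), glycolysis (0.279), oxidative phosphorylation (0.255), cholesterol handling (0.208; 0.0133 without labeled stroma 2), tip cell genes (0.969, with a positive median of 0.10 against a negative test) and extracellular matrix (0.294; 0.0209 without unlabeled stroma 1) did not pass.

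Microglia and astrocytes differed in how 84 of 13667 genes followed labeling (edgeR, library as a block), with 1295 under an unadjusted p of 0.05. Spock2, a proteoglycan of astrocytes and vessels, was 4.87 ± 0.43 more positive in astrocytes (adjusted p = 0.000415, edgeR), where its labeling difference was 0.56 against -4.37 in microglia. Epas1, a hypoxia-inducible factor of vessels, was 4.01 ± 0.47 more positive in astrocytes, the chemoattractant Rarres2 3.26 ± 0.43 and Hpgd 2.43 ± 0.39. Saa3, also a leading gene of border-associated macrophages, was more negative in astrocytes by -5.46 ± 0.64 (adjusted p = 0.00322, edgeR), with labeling differences of 5.88 in microglia and -0.48 in astrocytes. Of the 84 genes, 76 were more positive and 8 more negative in astrocytes, and 0 passed after subtraction of free RNA. Leaving out 1 library gave 166 genes without labeled stroma 1, 207 without labeled stroma 2, 258 without unlabeled stroma 1 and 301 without unlabeled stroma 2. The count was 0 with doublets kept, 0 with a doublet score under 0.25, 1 with a mitochondrial limit of 10% and 26 at a UMI minimum of 500. Between astrocytes and endothelial cells, 1 called gene was shared (Ttr, lower in both), against 0 on average for independent lists. Choroid plexus markers, Ttr among them, took 0.637% and 0.379% of UMIs in low-UMI barcodes of unlabeled and 0.0099% and 0.0078% in those of labeled stroma, and after subtraction of free RNA Ttr gave no value in either class.

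Cancer cells were split into 2 groups on fixed markers of the lines, so the match to those markers was set in advance, and KRT19, SPINT2, NNMT and CDH11 were higher in the group of the other line. HCC1954-BrM-like cells were 30.3% (29.3 to 31.2) of cancer library 1 and 60.9% (59.7 to 62.0) of cancer library 2, and the other cells were MDA231-BrM-like. HCC1954-BrM derives from a HER2-amplified ductal carcinoma and MDA231-BrM from a triple-negative, mesenchymal line. Higher in HCC1954-BrM-like cells were the antimicrobial peptide gene DCD (7.11 ± 0.48, adjusted p = 0.000133, edgeR) and the prolactin-induced PIP (6.98 ± 0.88). PALMD (6.77 ± 0.29), the steroid enzymes AKR1C2 (6.70 ± 0.48) and HSD17B2 (6.49 ± 0.40), the centriole gene CNTLN (6.63 ± 0.21), the chemokine CXCL17 (6.51 ± 0.58), the adhesion gene CEACAM6 (6.48 ± 0.58) and RARRES1 (6.48 ± 0.34) followed. The calcium-binding S100A14 (6.47 ± 0.23), S100A9 (6.40 ± 0.59) and S100A8 (6.33 ± 0.55) were higher as well, with S100A14 at 499 and 507 CPM against 5.6 and 6.7 CPM. Lower in HCC1954-BrM-like cells were the integrin adaptor APBB1IP (-6.43 ± 0.64, adjusted p = 0.000402, edgeR), the lipase inhibitor G0S2 (-6.21 ± 0.74), GYPC (-6.11 ± 0.64), ECI2 (-6.09 ± 0.69), SRGN (-6.06 ± 0.81) and GAMT (-6.05 ± 0.65). APOC1 (-5.99 ± 0.77), the detoxifying GSTP1 (-5.97 ± 0.82), SIVA1 (-5.94 ± 0.80), BASP1 (-5.90 ± 0.64) and the lactate dehydrogenase subunit LDHB (-5.90 ± 0.67) were lower too. The metastasis suppressor KISS1 (-5.95 ± 0.53) had 420 and 652 CPM in MDA231-BrM-like and 10.9 and 4.7 CPM in HCC1954-BrM-like cells. The 12 largest falls were all smaller in set 1 than in set 2, as in G0S2 (-5.12 and -7.88), and free RNA was not estimated for cancer cells. Of 16216 genes tested, edgeR called 9407, with 4679 higher and 4728 lower in HCC1954-BrM-like cells, and 11108 with the library as a block. Without either library the other one gives values but no test, since each library holds both lines.

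Of 31 epithelial adhesion and keratin genes, 26 were higher and 2 lower in HCC1954-BrM-like cells (camera, adjusted p = 9.17e-09, and adjusted p = 0.309 with an estimated correlation), led by LAD1 (6.29 ± 0.20), ST14 (5.58 ± 0.19), CDH3 (5.51 ± 0.23) and KRT23 (5.84 ± 0.26). The markers that split the cells included epithelial genes such as EPCAM and CDH1 and mesenchymal ones such as VIM and ZEB1. The shift of this list is therefore not independent of the split. Of 32 type I interferon genes, 24 were higher and 1 lower (0.000181, and 0.927 with an estimated correlation), with IFI44L (4.66 ± 0.30), CXCL10 (5.62 ± 0.43) and IFI6 (4.36 ± 0.34) higher and MX1 (-3.05 ± 0.22) lower. Cluster 11, led by ISG15, IFIT3 and IFIT1, held 700 cells, all HCC1954-BrM-like, and cluster 13, led by HERC5 and OASL, held 29 MDA231-BrM-like cells. Lists without a shift as a set held members that differed both ways. Extracellular matrix had 9 higher and 21 lower of 32 (0.102), with FBN1 at -5.47 ± 0.33 and FBLN1 at 5.09 ± 0.24. Mesenchymal genes had 11 higher and 15 lower of 29 (0.563), with ZEB2 at -5.31 ± 0.36 and ACTA2 at 5.24 ± 0.20. Brain colonization genes had 9 higher and 12 lower of 23 (0.563), with the adhesion molecule L1CAM at -4.24 and the phosphatase PTPRZ1 at 6.41. Glycolysis had 4 higher and 12 lower of 26 (0.215), oxidative phosphorylation 11 and 1 of 23 (0.0931) and cholesterol synthesis 11 and 3 of 24 (0.563). MHC class II had 5 higher and 7 lower of 13 (0.563), with CD74 at -4.71 ± 0.42, and MHC class I 3 and 5 of 19 (0.844, with a positive median of 0.06 against a negative test). NF-kB cytokines had 11 higher and 7 lower of 27 (0.563), with CCL2 at 5.61 ± 0.32; ERBB and PI3K signalling 6 and 9 of 24 (0.563), with PIK3R1 at 3.00 ± 0.18 and IRS1 at -2.74 ± 0.22. Proliferation had 5 and 6 of 24 (0.563) and stress genes 4 and 4 of 28 (0.786). Adjusted over the list alone, the counts were 26 and 2 for keratins and 24 and 1 for interferon genes.

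**Figure D4:**
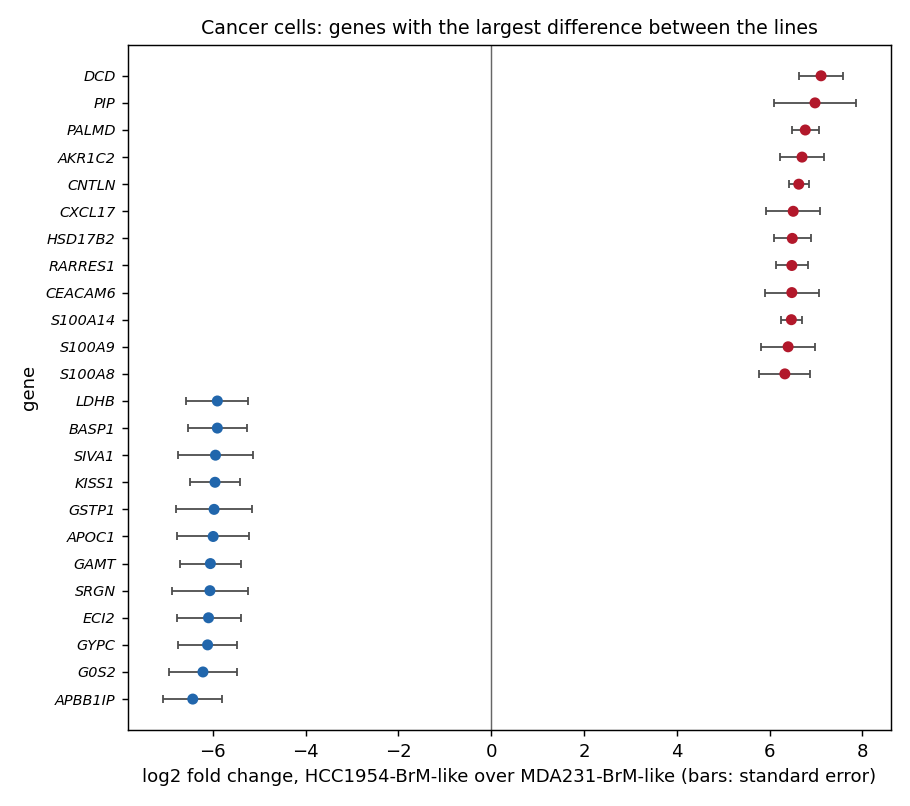
Log2 fold change, HCC1954-BrM-like over MDA231-BrM-like, of the genes with the largest differences, with SE as bars. DCD lay at 7.11 ± 0.48 and APBB1IP at -6.43 ± 0.64.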

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

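The free-RNA test of the first pattern, its criterion, the second comparison of cluster 31 with cancer cells and the test for damage or doublets were chosen only after the result was seen. The labeling effect differed between microglia and astrocytes in 84 genes by a test of the difference itself (edgeR, adjusted p). Genes such as Spock2 (4.87 ± 0.43 more positive in astrocytes) and Epas1 (4.01 ± 0.47) are genes of other cell types that were higher in microglia of unlabeled stroma. A test for doublets of microglia with such cells, which would concentrate the UMIs, pooled the 60 genes that were lower in labeled microglia. The 5% of microglia with the most UMIs of these genes held 18.2% and 21.3% of them in unlabeled stroma 1 and 2. In labeled stroma they held 16.9% and 16.7%. The pool also held genes that microglia express, such as Atf3, a leading gene of microglial cluster 6. Only 0.611% and 0.889% of unlabeled microglia had no UMI of the pool. Their own UMIs could hide those of doublets, so the test cannot decide. The count of 84 was 0 with doublets kept, 0 at a doublet score under 0.25, 1 with a mitochondrial limit of 10% and 26 at a UMI minimum of 500, and why was not tested. Free RNA stays open. After its subtraction the median absolute difference went from 3.5 to 4.93 and the median SE from 0.64 to 1.27, 80 of 84 genes kept their sign, and 0 passed (smallest adjusted p = 0.0847, edgeR), but 69 genes then had a zero sum in a library, against 8 before, which leaves the test without power to decide. A difference in how the cell types respond near cancer cells stays open as the biological explanation and was not tested.

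In unlabeled stroma 2, 3.6% of cells (287 of 7970) fell in cluster 31, outside every named class, against 0% in unlabeled stroma 1 and 0.25% and 0.18% in labeled stroma. Its leading genes included Vim (22100 CPM against 668 in the other cells of that library), S100a6 (17300 against 262) and H2afz (13700 against 319). Gm10036 (5590 against 72.3), Ost4 (4540 against 199), Gm9242 (1290 against 2.01) and Krt14 (634 against 0.514) were among them too. Damaged cells are argued against by the criterion used, with a median of 4749 UMIs per cell (6638 in the library). The median doublet score was 0.0115, against a criterion of at least 0.25. Called doublets had been removed before clustering, 167 in this library, where only 178 cells scored 0.25 or more. The score of the 287 cells left could hardly meet the criterion, so it cannot decide on doublets. Outside these criteria, the median was 1188 genes per cell (2437 in the library) and mitochondrial UMIs were 0.128% (5.22% in the library). Human cancer cells read against mouse genes were tested first on the whole profile, which went against them, since it correlated at 0.482 with the closer human line and at 0.604 with astrocytes (Spearman, across genes). Relative to the low-UMI barcodes of the library, a comparison added after that result, it correlated at 0.4 with the same line and at 0.338 with the closest mouse class, so human cells mixed with free RNA may be a candidate source. Of the fixed line markers 6 of 15 for HCC1954-BrM and 4 of 13 for MDA231-BrM were higher in the cluster, with Msn at 952 against 199 CPM but Sparc at 96 against 1590 and S100a4 at 0 against 10.6 CPM. The gate for GFP-negative cells would remove cancer cells, and how human reads map to a mouse reference was not measured. No biological explanation was tested.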

How the results depend on the processing

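A doublet score under 0.25, leaving out Gm42418 and AY036118, and free-RNA subtraction for the interaction and lists were chosen only after the results were seen. Across all alternatives 3886 values were taken as the same, of which 118 were counts that changed by at most 1.5 times. The other 3768 kept their side of the threshold and their direction, except that lists passing in neither setting could change direction. A further 350 became stronger, 299 weaker and 38 reversed, and 57 counts moved by over 1.5 times. Where no reason is given, the cause was not tested.

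With library number as a block, calls went from 0 to 2127 genes in microglia, 13 to 550 in astrocytes, 73 to 1700 in endothelial cells and 0 to 192 in ependymal cells, and from 0 to 9 classes for shares; set differences shared by both groups are removed there. Without the filter on low counts they were 689, 366, 1345 and 455, and 460 for the interaction (84 with it). DESeq2 called 223, 49, 518 and 27, and gave no adjusted p for 10331 genes in microglia and 2750 in astrocytes. DESeq2 size factors gave 30 genes in astrocytes and 167 for the interaction. With an estimated correlation 0 lists passed in each of the 5 comparisons, against 16, 14, 11, 13 and 2.

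Leaving out 1 library gave 0 to 175 genes in microglia, 53 to 464 in astrocytes, 2 to 376 in endothelial cells, 0 to 111 in ependymal cells and 166 to 301 for the interaction, 9 to 15 lists in astrocytes and 8 to 15 in ependymal cells; the lone sample is assumed to vary like the other group. The median of all astrocyte genes shifted by -0.11 without labeled stroma 2. Ranges over the library left out are given lowest to highest for results that reversed. Log2 values reached their lowest without labeled stroma 1 and their highest without unlabeled stroma 1 for microglial Acta2 (-8.70 to 0.47), Ddit4 (-4.05 to 0.80), Tsc22d3 (-3.88 to 1.07) and Adrb1 (-2.52 to 0.02), astrocyte Ccl4 (-2.86 to 14.22), endothelial Hbb-bs (-2.90 to 7.50), ependymal Mgp (-4.62 to 1.18) and Car3 (-2.66 to 0.63), and the shares of B cells (-1.05 to 1.67), NK or T cells (-1.74 to 0.74), neural progenitors (-11.36 to 5.16), neutrophils (-9.62 to 4.12) and oligodendrocytes (-11.47 to 1.69). B cells also reversed without unlabeled stroma 2 (-0.49) and NK or T cells without labeled stroma 2 (0.37). Lowest without labeled stroma 2 were the shares of astrocytes (-6.04 to 0.71) and dendritic cells (-3.95 to 0.16), both highest without unlabeled stroma 2, and of cycling neural progenitors (-4.66 to 1.75 without unlabeled stroma 1). Adjusted p (camera) ranged from 0.000502 to 0.039 for microglial stress genes (lower without labeled stroma 1, and without unlabeled stroma 2 at 0.0177), 0.0156 (lower, without labeled stroma 1) to 0.767 for astrocyte oxidative phosphorylation, 1.02e-07 to 0.881 for ependymal stress genes (0.31 without labeled stroma 1) and 4.26e-09 to 0.881 for ependymal ribosomal genes (0.0243 without labeled stroma 1).

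A UMI minimum of 500 gave 4 genes in astrocytes and 26 for the interaction. A minimum of 2000 left under 50 astrocytes in a library, so it gave no value for astrocytes or the interaction, and reversed the monocyte share (-2.98). A mitochondrial limit of 10% gave 0 genes in astrocytes, 5 in endothelial cells and 1 for the interaction, and reversed astrocyte Fbln2 (-0.62) and the shares of monocytes (-2.67) and cycling neural progenitors (0.05). With doublets kept, the counts were 1, 0 and 0, and endothelial Hbb-bs reversed (-3.26). A doublet score under 0.25 gave 0 genes in astrocytes, 37 in endothelial cells, 3 in ependymal cells and 0 for the interaction, and reversed Fbln2 (-0.54) and Hbb-bs (-9.51). Leiden resolution 2 gave 21 genes in astrocytes and 5 in endothelial cells, and reversed the monocyte share (-2.34). Without Gm42418 and AY036118 astrocytes had 24 genes.

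Free-RNA subtraction gave 99 genes in astrocytes, 0 for the interaction, 7 lists in endothelial cells and 8 in ependymal cells. It reversed microglial Crip1 (0.91) and astrocyte homeostasis (0.909), endothelial MHC class II (0.964) and astrocyte homeostasis (0.698), and ependymal Tagln (0.63), astrocyte homeostasis (0.00174) and blood-brain barrier genes (0.815). Depth limits astrocytes and endothelial cells of labeled stroma 1 most, with 58 and 60 cells.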

Other observations

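The test below was planned before its result was seen. The cluster with the most microglia differed between libraries: cluster 1 for labeled stroma 1 (30.8%), 8 for labeled stroma 2 (59.5%), 0 for unlabeled stroma 1 (73.5%) and 17 for unlabeled stroma 2 (52.4%). Clusters were also shared, as cluster 17 held 344, 260, 132 and 118 cells of these libraries. Dissociation stress and immediate early genes were higher in set 1 by a median log2 ratio of 3.79 in labeled and 4.48 in unlabeled microglia. A handling difference shared by all cells of a set could raise the same genes in every class. In astrocytes the medians were 1.51 and 1.36, in endothelial cells 0.8 and 0.64 and in ependymal cells 2.21 and 1.42, which gives 1.39 over these classes. The sign was shared, but the size lay between the bounds set beforehand, so handling and a difference between the sets' microglia cannot be told apart, and a difference in time or treatment is not excluded. No biological explanation was tested.

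Unnamed clusters besides cluster 31 also held different shares of the groups. Cluster 18, led by Hba-a1, Ctsk, Acp5 and Mmp9, was 4.24% and 3.42% of labeled and 0.66% and 0.49% of unlabeled stroma. Cluster 21, led by Npy, Serpina3n and Fabp7, was 0.45% and 5.26% of labeled and 2.25% and 2.32% of unlabeled stroma. Monocytes or monocyte-derived cells were 4.76% and 2.41% of labeled and 2.41% and 0.402% of unlabeled stroma, and pericytes 0.283% and 0.285% against 1.79% and 0.966%. The monocyte difference reversed in 3 alternatives (-2.98, -2.67 and -2.34), where monocytes of labeled stroma 1 went from 606 to 11, 21 and 26 cells. Fibroblasts were 2.35% and 5.54% against 0.357% and 3.78%, but 234 of the 301 in unlabeled stroma 2 were cluster 33, with 0 fibroblast markers among its 10 leading genes, and that library held 69 at a UMI minimum of 500 and 67 at Leiden resolution 2.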
